A study of Mus musculus with 8 samples.

How the data were processed

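Gene expression was measured in bone marrow-derived macrophages of male C57BL/6J mice, which are macrophages grown in culture from bone marrow precursors. Cells from 4 mice were each studied under 2 conditions, transfection with a control siRNA and transfection with siRNA directed at the terminal loop of the Y RNAs, which gives 8 samples in 2 groups of 4. The replicate numbers in the labels are used as mouse 1 to mouse 4 below. The siRNA sequences, dose and time after transfection are not given in the sources used here. Total RNA (0.2 µg per sample) was labelled with Cy3 and hybridised to 1-colour Agilent mouse arrays, per the labels' protocols. The RNA integrity number was 10 for 7 samples and 8 for control replicate 4.

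The deposited scanner files hold intensity values per spot, made with Agilent Feature Extraction 10.7.3.1 and the protocol GE1_107_Sep09, per the file headers. The processed signal in them is a linear intensity from which background was subtracted and spatial trends were removed, with no normalization between arrays, per the file headers. The raw mean, raw median and local background intensities are given beside it. The array design is 028005, with probe positions on mouse genome build mm9. All 8 arrays lay on 1 slide and were scanned in 1 session, so neither slide nor scan could differ between the groups. The arrays of the Y RNA siRNA lay in slide columns 1 and 3 and the control arrays in columns 2 and 4, so column and group cannot be told apart. Mice 1 and 2 lay in slide row 1 and mice 3 and 4 in row 2, with both groups in each row. The authors' deposited value table holds log2 values with a common maximum of 18.6 and column medians from 6.26 to 6.27, and the lowest correlation of a column was 0.9998, with the log2 raw median signal of the same array. The method and the centring behind that table are not stated, and it was used as an alternative only.

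Each array holds 62976 spots, of which 3671 are control spots and were left out. The main values are log2 of the processed signal minus the 75th percentile of that quantity on the same array, averaged over the spots of a probe. The 75th percentile of the log2 processed signal ranged from 9.04 to 9.34 between arrays and was lowest on both arrays of mouse 1. Between 48.7% and 50.7% of the spots of an array were well above background, and 0 spots were saturated. Probes well above background on at least 4 of the 8 arrays were kept, which left 26818 of 55681 probes. Accessions of 26762 probes matched a RefSeq table for GRCm38.p6, which was used for names only, and 2878 probes took a newer symbol from it. A gene with several kept probes was represented by the probe with the highest mean signal over all 8 arrays, giving 19284 genes, of which 14311 have a gene symbol and 4973 carry another identifier.

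The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Adjusted p-values below are from limma unless another test is named. Standard errors are those of the moderated fit. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists that had at least 5 tested members. The 33 lists, with 941 entries of which 917 have a probe, were fixed before the data were examined, as were the tests, the alternatives apart from those named as added, and the rule for naming genes. They cover inflammatory cytokines and chemokines, the NF-kB pathway and its feedback, interferon-stimulated genes, RNA and DNA sensing, apoptosis (pro-death and pro-survival), p53 targets, DNA replication, mitosis and the cell cycle, histone genes, partner proteins of Y RNA and of Ro60 and La, small RNA processing, cholesterol synthesis, LXR targets and cholesterol efflux, scavenger and phagocytic receptors, alternative activation, macrophage identity, antigen presentation, the unfolded protein response, the oxidative stress response, heat shock proteins, immediate early genes, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins and the lysosome. Markers of dendritic cells, neutrophils, lymphocytes, erythroid cells and megakaryocytes, fibroblasts, osteoclasts, and mast cells and basophils make up the rest.

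The rule names the 12 genes with the largest rise and the 12 with the largest fall past the threshold that move the same way in all 4 mice, filled up by the smallest unadjusted p where fewer pass, skipping olfactory, predicted and unnamed genes. It also names up to 4 members with the smallest p from each list described, and always Rny1, Rny3, Trove2 (now Ro60) and Ssb.

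The series design states 2 conditions on 4 mice, and the arrays were checked for pairing before the fits were compared. After subtracting the group means, the 2 arrays of a mouse correlated at 0.597, 0.152, 0.574 and 0.284 for mice 1 to 4, so the replicate numbers were taken to pair the samples. For 7 of the 8 arrays the best partner in the other group was the array with the same number, and control replicate 2 correlated best with replicate 3 of the Y RNA siRNA, so the pairing of mouse 2 is the least certain. The mouse was fitted as a fixed block and, with duplicateCorrelation (statmod 1.5.0), as a random block with a consensus correlation of 0.53. The random block gives every gene this same correlation, although genes can differ in it. Other alternatives were the slide row as a block, normexp background correction with an offset of 50, quantile normalization, median centring, the deposited value table, no filter on dim probes, a filter on all 8 arrays, spots marked as poor left out, the mean of a gene's probes, eBayes with trend and robust, array weights, other thresholds, each array and each mouse left out, camera with an estimated correlation, and fry. A few combinations of these with the mouse block were added after the values had been seen. A fit without 1 array keeps its mouse in 1 group only, so the difference of that mouse from the others enters the siRNA comparison. Such fits therefore also measure differences between mice.

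The fits were tested on simulated data with the real means, the real spreads shuffled among genes, and the mouse correlation. They held 19284 genes, 200 of them changed in equal parts by 1.25, 1.5, 2 and 4-fold. Each gene was drawn independently, so genes did not move together as they can on the arrays. Every gene was also given the same mouse correlation, which is what the random block assumes. The simulation therefore does not show how the random block performs where genes differ in that correlation. For the comparison of the Y RNA siRNA with the control, the fit without a block recovered 28% of the genes changed by 1.25-fold, 56% at 1.5-fold, 72% at 2-fold and 92% at 4-fold. The random block recovered 42%, 70%, 84% and 98% of them. With no gene changed, 0 genes were called by either, and 277 genes had an unadjusted p under 0.05 without a block, against 1062 with the fixed block. A list of the comparison shifted by 0.3 (log2) in these data was called by camera, with 0 of the other lists called. That shift is larger than the list medians reported below. As the genes were independent, this does not test whether camera calls lists falsely when their members move together. Of 100 genes shifted 2-fold in 1 mouse, the F-test between mice called 64%, and it called 159 others, which carry the mouse differences that the simulation gives every gene. Figures were drawn with matplotlib 3.10.9.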

Results

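Bone marrow-derived macrophages from 4 mice were profiled after transfection with siRNA against the terminal loop of the Y RNAs or with a control siRNA. Y RNAs are small noncoding RNAs bound by the proteins Ro60 and La, and small RNAs cut from them are called s-RNYs. The series sets out to find genes that respond to s-RNYs in these cells. Each group held 4 arrays, 1 per mouse. The 8 arrays correlated with one another at Pearson's r of 0.989 to 0.997 over 19284 genes. Levels below are log2 signals relative to the 75th percentile of the array, and changes are the Y RNA siRNA minus the control.

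The first component of variation separated mouse 1 from the other mice, not the siRNA groups. Component 1 held 42.6% of the variance and set both arrays of mouse 1 apart from the other 6, and component 2 held 14.9%.

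**Figure D1:**
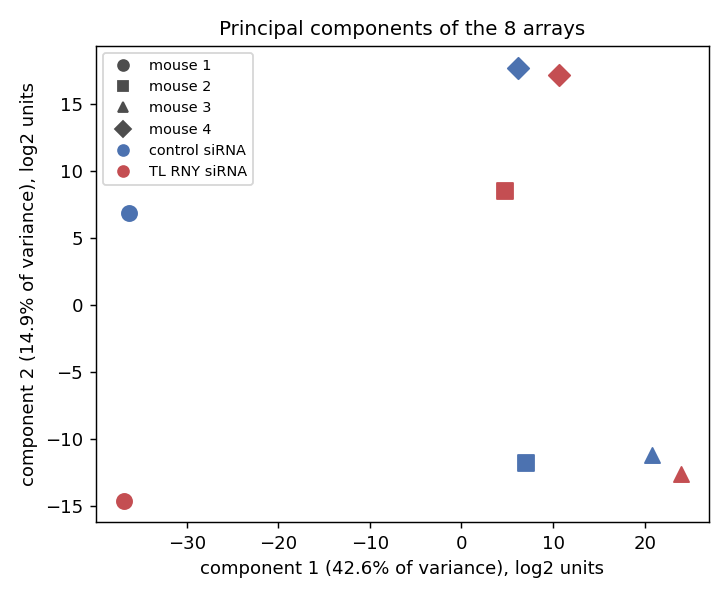
Principal components 1 and 2 of the 8 arrays over 19284 genes, with axes in log2 units. Colours mark the siRNA group and symbols the mouse, and both arrays of mouse 1 lie at the far left of component 1, which holds 42.6% of the variance.

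Transfection with the Y RNA siRNA was followed by small differences in signal, and no single gene passed the threshold. Among genes with a symbol, the differences nearest to it were a higher signal of Trnp1, a nuclear protein known from the proliferation of neural progenitors, and of Cst7, which encodes cystatin F, an inhibitor of cysteine proteases in immune cells. Btbd11, with a lower signal, and Eng, with a higher one, came next. Rngtt, the mRNA capping enzyme, was further from the threshold, with a log2 fold change of -0.38 on the probe used and -0.20 as the mean of its 2 probes. Trnp1 was 1.80-fold higher and Cst7 1.54-fold higher on average, and the median gene differed by 0.06 on the log2 scale. Ro60 and Ssb, the genes of the Ro60 and La proteins that bind Y RNAs, differed by less than their standard errors.

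In limma, 0 of 19284 genes had an adjusted p under 0.05, with 654 at an unadjusted p under 0.05, against 964.2 expected by chance. The smallest adjusted p was 0.0828. With the mouse as a fixed block, 0 genes passed and 1777 had an unadjusted p under 0.05. A simulated data set with the same mouse correlation and no changed gene gave 277 without a block and 1062 with the fixed block. It drew genes independently, so it does not show how far such counts scatter. Regrouping the arrays in other ways that part the arrays of every mouse gave 190 to 695 without a block and 424 to 1363 with the fixed block. With the mouse as a random block, 11 genes passed between the real groups, 7 higher and 4 lower. The same direction in all 4 mice was seen for 19.3% of genes, against 12.5% by chance. The 95% interval excluded a 2-fold change for 95.5% of genes and a 1.5-fold change for 84.6%. Without a block the p-values measure the spread among the arrays of each group, and with the fixed block the spread of the differences within mice. All of them rest on these 4 mice.

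Trnp1 (probe on chromosome 4, 133047017 to 133047076, mm9) had a level of -1.44 ± 0.06 (SD, n = 4) in controls and -0.60 ± 0.13 (SD, n = 4) with the Y RNA siRNA. Its log2 fold change was 0.85 ± 0.08 (SE), or 0.56 as the mean of its 2 probes, higher in 4 of 4 mice, with an adjusted p of 0.0828 without a block, 0.201 with the fixed block and 0.00737 with the random block. Cst7 (chromosome 2, 150404490 to 150404549) went from 0.08 ± 0.12 to 0.70 ± 0.07 (SD), a log2 fold change of 0.62 ± 0.07 (SE) in 4 of 4 mice. Its adjusted p was 0.204 without a block and 0.0112 with the random block. Eng (chromosome 2, 32537268 to 32537327), which encodes endoglin, a coreceptor for TGF-beta, had closely spaced values, with 1.37 ± 0.03 in controls and 1.70 ± 0.03 with the Y RNA siRNA (SD). Its log2 fold change was 0.33 ± 0.05 (SE). The adjusted p was 0.379 without a block, 0.235 with the fixed block and 0.0406 with the random block. Btbd11 (chromosome 10, 85122975 to 85123034) went from 0.17 ± 0.06 to -0.29 ± 0.06 (SD), a log2 fold change of -0.45 ± 0.06 (SE). Its adjusted p was 0.225 without a block, 0.235 with the fixed block and 0.0406 with the random block. In mouse 3, Eng was lowest among the controls (1.333) and highest with the Y RNA siRNA (1.745). Btbd11 was there highest among the controls (0.2318) and lowest with the Y RNA siRNA (-0.3795). The random block still applied its shared positive correlation of 0.53 to both genes.

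The random block also called Syt11, a synaptotagmin of vesicle traffic (log2 fold change 0.40), the calpain protease Capn9 (0.52) and the zinc finger genes Zfp820 (0.45) and Zfp982 (0.37) as higher. The last 3 are dim, and with normexp, which adds an offset, Capn9 was at 0.20, Zfp820 at 0.29 and Zfp982 at 0.19. It called Rngtt (-0.38, or -0.20 as the mean of its 2 probes) and Fcna, the secreted lectin ficolin A (-0.50), as lower, together with a probe without a gene symbol, A_55_P2069530 on chromosome 6 (47731682 to 47731741). That probe had a log2 fold change of -1.08 ± 0.12 (SE) and an adjusted p of 0.145 without a block, and it falls outside the naming rule and was chosen after its values were seen. All 11 of these calls were lost when any 1 of the 4 mice was left out of the random block fit, each time with 0 genes called. Their log2 fold changes stayed between 88.2% (Btbd11 without mouse 3, -0.40) and 111% (Capn9 without mouse 3, 0.57) of the value from all 4 mice. The test picks genes whose differences are alike in these same mice, so this narrow range is no separate evidence. The lost calls do not show that the differences rest on 1 mouse either. The random block called 14 genes on quantile values, all 11 among them, and 17 genes with the deposited value table, 8 of the 11 among them.

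The other genes named by the rule passed neither without a block nor with either block, and each moved the same way in 4 of 4 mice. On the higher side were Tnfsf13b, the B cell survival cytokine BAFF, at 0.41, the lipid hydrolase Abhd6 at 0.47, BC052527 at 0.64, the transmembrane prolyl hydroxylase P4htm at 0.53 and Dnajc18 at 0.26. On the lower side were Spopl at -0.30, the B cell scaffold gene Bank1 at -0.47, Defa-rs7 at -0.30, Aco1, the cytosolic aconitase that also regulates iron genes, at -0.27, and Zc3h12d at -0.37. Pheta1 at -0.29, the endoplasmic reticulum chaperone gene Erp44 at -0.23, the inactive rhomboid gene Rhbdf1 at -0.38 and Tor1aip2 at -0.28 completed the 12. The 2 probes of Tor1aip2 disagreed in direction, with a mean of -0.11. With normexp the dim genes among these were nearer 0, with Abhd6 at 0.19, BC052527 at 0.24, P4htm at 0.27 and Defa-rs7 at -0.059.

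No probe on the array is named for Rny1 or Rny3, so the knockdown of the Y RNAs themselves was not checked. The 22077 probes without a gene symbol were not searched by position, and the unnamed probe A_55_P2069530 was not matched to a gene. Ro60 had a log2 fold change of 0.05 ± 0.07 (SE) and Ssb one of -0.02 ± 0.07 (SE), and Ssb had 2 probes that disagreed in direction and a log2 fold change of 0.0077 with median centring.

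**Figure D2:**
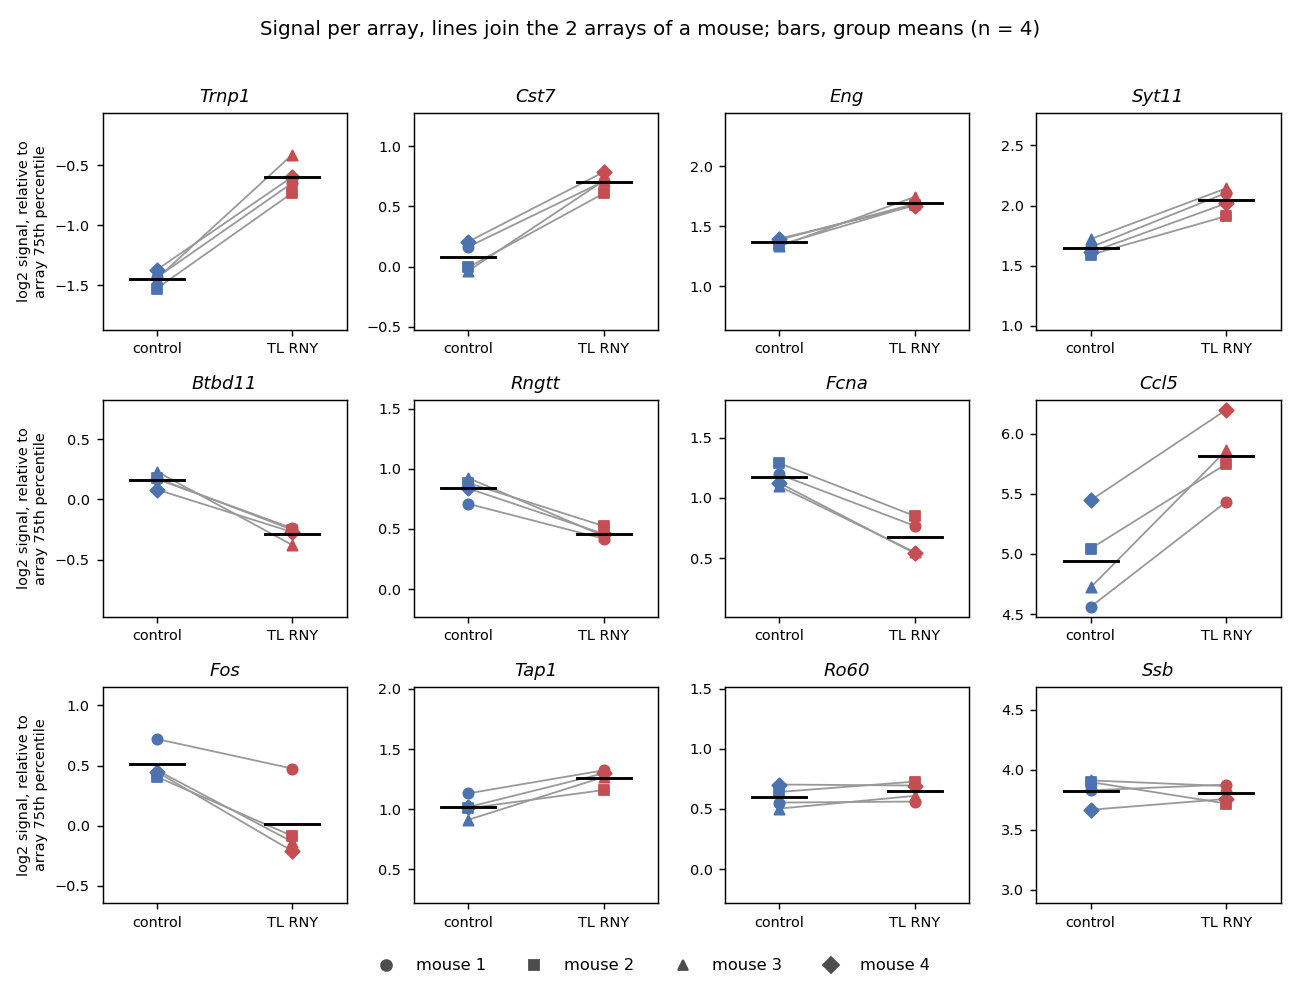
Signal of 12 genes on each array, as log2 relative to the 75th percentile of the array, with control siRNA at left and the siRNA against the Y RNA terminal loop at right. Lines join the 2 arrays of a mouse, bars are group means (n = 4), every vertical axis spans the same range, and none of the 12 genes passed the adjusted threshold without a block.

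Among the gene lists, interferon-stimulated genes rose and immediate early genes fell by small amounts in camera with a preset correlation. Neither passed with an estimated correlation (adjusted p = 0.956 and 0.701) or with fry (0.992 for both). Before adjustment over the lists, p was 0.456 and 0.0219 in camera with an estimated correlation, and 0.507 and 0.0412 in fry. With the mouse as a fixed block, neither passed with an estimated correlation (adjusted p = 0.928 for both) or with fry (0.605 and 0.0819). Of 38 interferon-stimulated genes tested, 36 were higher with the Y RNA siRNA, and the median log2 fold change was 0.10. Of 23 immediate early genes, 18 were lower, with a median of -0.06. Both shifts went one way in 4 of 4 mice, as did those of 5 lists that did not pass (alternative activation, osteoclast markers, pro-survival genes, scavenger receptors and inflammatory genes). Without a block, 0 members of either list passed on their own, over all genes or adjusted over the list alone. With the mouse as a fixed block, 7 immediate early genes passed adjusted over the list alone.

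For interferon-stimulated genes camera gave an adjusted p of 0.0284, and the adjusted p was 0.956 with an estimated correlation and 2.03e-05 with the mouse as a fixed block. The mean shift was 0.05, 0.09, 0.25 and 0.01 in mice 1 to 4. Its members with the smallest p were the RNA sensors Ifih1 (log2 fold change 0.13 ± 0.09, SE) and Ddx58 (0.11 ± 0.08, and 0.018 as the mean of 2 probes that disagreed), tetherin, Bst2 (0.17 ± 0.12), and Trim30a (0.10 ± 0.07). The call was lost without control replicate 1 (adjusted p = 0.690, median 0.02), control replicate 3 (0.101, median 0.09) or replicates 2 (0.169, median 0.08), 3 (0.176, median 0.07) or 4 (0.356, median 0.04) of the Y RNA siRNA. It was also lost without both arrays of mouse 3 (0.573, median 0.04), with median centring of the arrays (0.0679) and with no filter on dim probes (0.144). The median was higher without replicate 1 of the Y RNA siRNA (0.23, adjusted p = 1.51e-09) and without control replicate 4, the array with the lower RNA integrity number (0.18, 2.74e-06). A fit without 1 array keeps its mouse in 1 group only, so that mouse's difference from the others enters the comparison. In mouse 1 the list lay at -0.29 relative to the mean of the 4 mice. Without both arrays of mouse 1 the median was 0.115 (adjusted p = 3.84e-07).

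For immediate early genes, which respond first to stimulation, the adjusted p was 0.0297, and it was 0.701 with an estimated correlation and 0.000690 with the mouse as a fixed block. The mean shift was -0.09, -0.08, -0.12 and -0.16 in mice 1 to 4. Fos had the largest difference among the 4 members named (log2 fold change -0.50 ± 0.16, SE), beside Klf4 (-0.16 ± 0.06) and Klf2 (-0.26 ± 0.12), while Maff was higher (0.26 ± 0.14, and 0.12 with normexp). With the mouse as a fixed block, 7 members passed adjusted over the list alone, namely Atf3, Egr1, Egr2, Fos, Klf2, Maff and Nr4a1. The call was lost without control replicate 1 (adjusted p = 0.0523) or 4 (0.0535), and without replicate 2 (0.103), 3 (0.0622) or 4 (0.0728) of the Y RNA siRNA. It was also lost without both arrays of mouse 3 (0.106) or of mouse 4 (0.148), with medians between -0.10 and -0.06 in these cases. The median was further from 0 without both arrays of mouse 1 (-0.13, adjusted p = 0.000806) and without replicate 1 of the Y RNA siRNA (-0.11, 0.0106).

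With the mouse as a fixed block, camera called 4 lists, adding antigen presentation and DNA replication. Neither of these passed with an estimated correlation and the block (adjusted p = 0.928 for both). Antigen presentation had 17 of 20 members higher, a median of 0.07 and an adjusted p of 0.0645 without and 0.00689 with the block, but the mean shift was 0.08, 0.14, 0.14 and -0.08 in mice 1 to 4. Its named members were the peptide transporter Tap1 (log2 fold change 0.25 ± 0.06, SE), Nlrc5, the activator of MHC class I genes (0.16 ± 0.06), the immunoproteasome subunit Psmb9 (0.13 ± 0.05) and Ctss (-0.11 ± 0.05). DNA replication genes had 41 of 46 members higher, a median of 0.09 and an adjusted p of 0.0806 without and 0.0201 with the block, but the mean shift was 0.33, -0.24, 0.09 and 0.19 in mice 1 to 4. Rfc2 (0.10 ± 0.05), Rfc1 (0.11 ± 0.08), Dbf4 (0.13 ± 0.10) and Orc4 (-0.10 ± 0.06) were its members with the smallest p. Without a block antigen presentation passed with normexp (adjusted p = 0.0389), quantile (0.0331), both (0.00922), the deposited table (0.00827) and array weights (0.00190), and without control replicate 1 (0.0190) or 4 (0.00117), replicate 3 of the Y RNA siRNA (0.00482) or mouse 4 (0.00569). DNA replication passed with normexp and quantile (0.0396), the deposited table (0.0448) and array weights (0.0348), and without control replicate 2 (4.55e-05) or 3 (1.01e-06), replicate 1 (0.00539) or 4 (0.0306) of the Y RNA siRNA, or mouse 2 (1.22e-05). With an estimated correlation, 0 of the 32 lists passed either without or with the block, and fry gave 0 as well.

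Inflammatory genes did not shift as a group. Of 17 inflammatory cytokines and chemokines tested, 7 were higher (adjusted p = 0.991). Ccl5, a chemokine for T cells and monocytes, stood apart with a log2 fold change of 0.87 ± 0.22 (SE), higher in 4 of 4 mice. Its adjusted p over all genes was 0.976 without a block, 0.201 with the fixed block and 0.0867 with the random block. With the fixed block Ccl5 and Ccl12 passed adjusted over the list alone. Cxcl2 (0.39), Ccl3 (-0.08) and Cxcl11 (-0.09) were the other members named, and Cxcl2, at 0.11 with normexp, was well above background on 2 of 4 control arrays and 3 of 4 arrays of the Y RNA siRNA. In the NF-kB list 17 of 31 members were higher (adjusted p = 0.539), with Tnfaip3, the A20 feedback inhibitor, at -0.20 ± 0.07 (SE), Tnip3 at -0.17, Tnfaip2 at -0.19 and Traf1 at 0.20. In the RNA and DNA sensing list 12 of 23 were higher (adjusted p = 0.990), with Sting1 at 0.12, Irf5 at -0.11, Tlr3 at -0.22 (-0.13 with normexp) and Cgas at 0.13.

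Cell death genes did not shift as a group either. Of pro-death genes 11 of 27 were higher (adjusted p = 0.894), and of pro-survival genes 15 of 19 (adjusted p = 0.845). Pmaip1, the BH3-only protein Noxa, was at -0.27 ± 0.15 (SE), Endog at -0.11, Casp8 at -0.05 and Tnfsf10, the death ligand TRAIL, at 0.19 (0.096 with normexp). With the mouse as a fixed block Pmaip1 passed adjusted over the list alone, in the pro-death list and among p53 targets. Xiap, an inhibitor of caspases, was at -0.11 ± 0.05 (SE), Naip5 at -0.09, Naip2 at 0.10 and Birc6 at 0.05 (0.021 with normexp). Of p53 targets 18 of 23 were higher (adjusted p = 0.539). Among partner proteins of Y RNA, Ro60 and La, 11 of 23 were higher (adjusted p = 0.895). Nucleolin, Ncl, was at 0.09 ± 0.05 (SE) and at -0.0086 as the mean of its 2 probes, which disagreed, Calr at -0.22 and Fip1l1 at 0.08. Zbp1, at 0.25, is counted in this list and also in the interferon-stimulated one. Its symbol is that of the Z-DNA binding protein, not of the zipcode-binding protein, whose gene Igf2bp1 the fixed list names separately. Small RNA processing genes had 13 of 22 members higher (adjusted p = 0.813).

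Mitosis and cell cycle genes had 36 of 42 members higher with a median of 0.06 (adjusted p = 0.313), although Cenpf was at -0.65 ± 0.22 (SE), or -0.23 with normexp, and Cdc20 at -0.13, beside Ccnd2 at 0.26 (0.13 with normexp) and Nek2 at 0.19, the last at -0.0014 with array weights. The mean shift was 0.29, -0.28, 0.05 and 0.14 in mice 1 to 4. With an estimated correlation the adjusted p was 0.956, and with the preset one the list passed with array weights (adjusted p = 0.00114), without control replicate 2 (0.000847) or 3 (3.53e-05), without replicate 4 of the Y RNA siRNA (0.0306) and without mouse 2 (3.24e-05). Histone genes had 33 of 43 members lower with a median of -0.08 (adjusted p = 0.210), with H2bu2 at 0.50, Hist1h4i at 0.17, H2ac8 at -0.25 and H2ac6 at -0.52, the last well above background on only 1 of 4 arrays of the Y RNA siRNA. With normexp these were at 0.25 (H2bu2), -0.088 (H2ac8) and -0.15 (H2ac6). The mean shift was 0.04, -0.26, -0.11 and 0.06, the adjusted p was 0.956 with an estimated correlation, and with the preset one the list passed with array weights (0.00190), without control replicate 4 (0.000163) and without mouse 4 (0.000924). Alternative activation genes had 13 of 17 members lower with a median of -0.06 (adjusted p = 0.253), and named members were Pdcd1lg2 at -0.39, or -0.15 with normexp, whose 2 probes disagreed, Klf4 at -0.16, Il4ra at 0.21 and Il10 at -0.16. Macrophage identity genes had 17 of 28 members lower (adjusted p = 0.539), with the lineage regulators Cebpa at -0.16 and Spi1 at -0.10, and Maf at 0.10. Without control replicate 1 alternative activation passed (0.0462), and without control replicate 3 macrophage identity did (0.0405), as did the NF-kB list (0.0459), while with an estimated correlation on all 8 arrays the adjusted p was 0.956 for each of these 3.

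No metabolic or stress list passed with all 8 arrays and no array weights on the main values. The adjusted p was 0.845 for cholesterol synthesis, 0.539 for LXR targets, 0.895 for scavenger and phagocytic receptors, 0.895 for the lysosome, 0.539 for hypoxia and glycolysis, 0.538 for oxidative phosphorylation and 0.287 for ribosomal proteins. Ribosomal proteins passed with the deposited table (0.00357), normexp with quantile (0.00922), array weights (0.0180), without control replicate 1 (0.00257) and without replicate 3 of the Y RNA siRNA (0.000421). With an estimated correlation its adjusted p was 0.956, and the same value held for oxidative phosphorylation, cholesterol synthesis and fibroblast markers. Oxidative phosphorylation passed with array weights (0.00150), without control replicate 1 (0.00113) and without mouse 1 (0.00472), and cholesterol synthesis without control replicate 1 (0.0190). The adjusted p was 0.539 for the unfolded protein response, 0.287 for the oxidative stress response and 0.895 for heat shock proteins. Markers of other cell types did not pass with all 8 arrays, with an adjusted p of 0.895 for dendritic cells, 0.636 for neutrophils, 0.895 for lymphocytes, 0.895 for erythroid cells and megakaryocytes, 0.539 for fibroblasts and 0.539 for osteoclasts. Fibroblast markers passed without control replicate 1 (8.74e-05) and without mouse 1 (0.0268). Mast cell and basophil markers had 4 tested members and were not tested, and their median was 0.13. The median, the mean and the camera direction differed in sign for the inflammatory, NF-kB, RNA and DNA sensing, pro-death, Y RNA partner, unfolded protein, heat shock, scavenger receptor, neutrophil, lymphocyte and dendritic cell lists. Over all 32 lists, 0 members passed adjusted over the list alone without a block, and 18 entries in 9 lists did with the mouse as a fixed block.

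**Figure D3:**
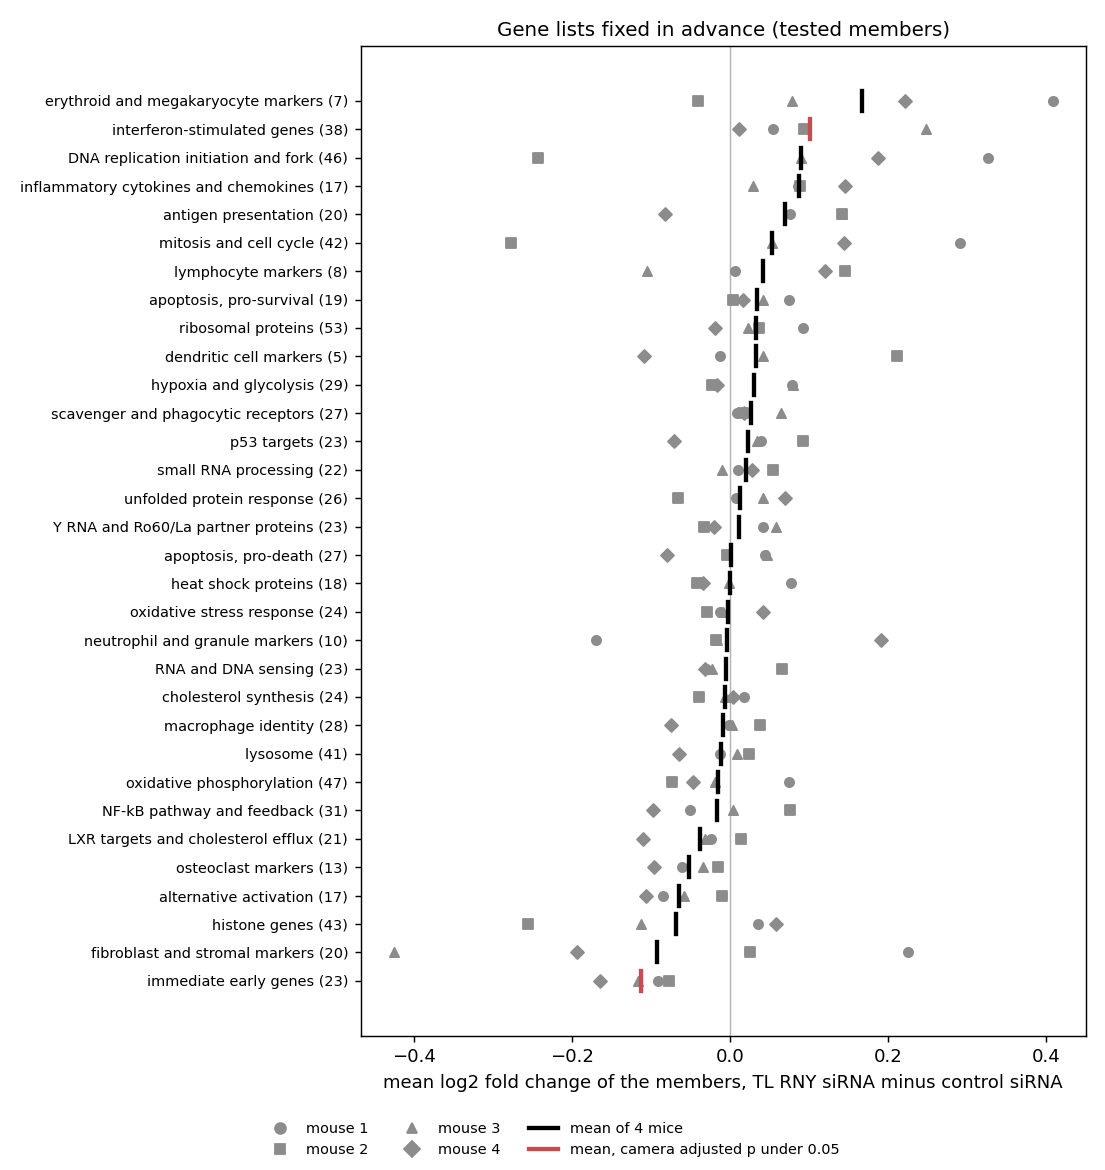
Mean log2 fold change of the members of each of the 32 lists tested, as the siRNA against the Y RNAs minus the control, per mouse (grey symbols) and over the 4 mice (bars, red where camera's adjusted p was under 0.05). The 4 mice lie on one side of 0 for interferon-stimulated and immediate early genes and for 5 lists that did not pass, and on both sides for DNA replication, where they range from -0.24 to 0.33.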

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

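In 236 groups of 4 arrays, made of the list means, genes chosen for the report and 4 array measures in each siRNA group, 19 held an array far from the other 3, where chance gives about 1 in 20, or 11.8. Of the 19 arrays 12 belonged to mouse 1. All values below are log2 signals relative to the 75th percentile unless stated, and none has been given an explanation.

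On the array of the Y RNA siRNA from mouse 1, the list mean was 2.10 for pro-death genes against 2.01 to 2.02 on the other 3 arrays of the group, 0.51 for immediate early genes against 0.39 to 0.41, 5.62 for the lysosome against 5.73 to 5.74, and -0.61 for lymphocyte markers against -0.72 to -0.71. On that array Ddx58 was at 4.27 (others 4.41 to 4.43), Klf2 at 2.22 (1.85 to 1.90) and Fip1l1 at 2.99 (3.16 to 3.18). On the control array of mouse 1, the list mean was 3.01 for pro-survival genes against 3.13 to 3.14, 2.71 for partner proteins of Y RNA against 2.92 to 2.95, and 5.41 for oxidative phosphorylation against 5.53 to 5.55. There Pheta1 was at 2.78 (others 2.69) and Spi1 at 1.46 (1.20 to 1.24).

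On the array of the Y RNA siRNA from mouse 3, the list mean was 1.46 for small RNA processing against 1.53 and 4.32 for antigen presentation against 4.48 to 4.51, and Cgas was at 2.38 (others 2.12 to 2.16). On that of mouse 2, Dnajc18 was at 1.70 (others 1.80 to 1.81), and on that of mouse 4, Tlr3 was at -2.37 (others -2.70 to -2.69). On control replicate 4, the array with the RNA integrity number of 8, Bank1 was at -0.75 (others -0.49 to -0.45), and the mean net signal of the negative control spots was 40.8 intensity units against 44.6 to 45.1 on the other 3 control arrays.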

How the results depend on the processing

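Some combinations with the mouse block, named below as added, were chosen only after the values were seen. The count of 0 genes was the same with the mouse or the slide row as a fixed block, with normexp, quantile or median scaling, with the deposited table, with poor spots left out, with either other filter, with the mean of a gene's probes, with trend and robust, and without each array or mouse (0 to 0). It was 11 with the mouse as a random block, 1 with array weights (Trnp1), 1 at an adjusted p under 0.10, and 46 at an unadjusted p under 0.05 with a fold over 1.5. Among the added ones it was 3 with normexp and the fixed block, 2 with the deposited table and the fixed block, 14 with the random block on quantile values (all 11 of the random block calls among them) and 17 with the random block on the deposited table (8 of them). The count of 2 lists became 4 with the fixed and 4 with the random block, 5 with normexp and quantile, 5 with the deposited table, 1 with median centring, 1 with no filter, 8 with array weights, 0 with an estimated correlation, 0 with fry, and 0 to 6 without single arrays or mice. In all, 11 lists with no call passed in at least 1 of these settings. For interferon-stimulated genes the median was 0.13 with median centring (adjusted p = 0.0679) and 0.10 with no filter (0.144), an estimated correlation (0.956) or fry (0.992). Without single arrays or mice it ranged from 0.019 to 0.23, with an adjusted p from 1.51e-09 to 0.690, under 0.05 in 6 of 12 cases. The cases without a single array also carry the difference of its mouse from the others. For immediate early genes it was -0.063 with an estimated correlation (0.701) and -0.063 with fry (0.992), and it ranged from -0.13 to -0.061 without single arrays or mice, with an adjusted p from 0.000806 to 0.148, under 0.05 in 5 of 12 cases. Of the 82 genes chosen, 18 had a log2 fold change smaller by over 1.5 times with normexp and 20 with the deposited table, most of them dim, and 3 changed sign in some setting. Ssb (-0.022 on the main values) was at 0.0077 with median centring and from -0.075 to 0.031 without single arrays or mice, Ncl (0.094) at -0.0086 with the mean of its probes, and Nek2 (0.19) at -0.0014 with array weights.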

Other observations

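The mice differed more than the siRNA groups. With the siRNA group in the model, 900 of 19284 genes (4.67%) differed between the 4 mice at an adjusted p under 0.05 (limma's F-test), and mouse 1 lay farthest from the mean of the 4 mice for 696 of them. Set against the other 3 mice, mouse 1 differed in 2789 genes, mouse 2 in 36, mouse 3 in 589 and mouse 4 in 57. The mice that mouse 3 was set against include mouse 1. Compared in pairs, mouse 1 differed from mice 2, 3 and 4 in 753, 3319 and 806 genes. Mice 2 and 3 differed in 11 genes, mice 2 and 4 in 9, and mice 3 and 4 in 21. The differences between mice were thus mainly those of mouse 1. The genes below were chosen after their values had been seen. Chil3, the chitinase-like protein Ym1 of alternatively activated macrophages, was at -3.66 in mouse 1 and at 1.74, 3.32 and 2.98 in mice 2, 3 and 4 (adjusted p = 0.000182). Bex1 was at -2.53 in mouse 1 and at 2.51, 3.65 and 2.77 in the others. Ctsk, the collagenase cathepsin K, was at 2.62 against 5.09, 5.63 and 5.36, and the chemokine gene Ccl2 at 1.62 against 3.51, 4.76 and 3.34. The transferrin receptor gene Tfrc was lower in mouse 1 than in the mean of the others by a log2 difference of -2.72. Retnla, Arg1 and Scd1 were not well above background on either array of mouse 1 and were on both arrays of the other mice. Higher in mouse 1 were Axl (2.53 against 0.93, 1.20 and 1.39), a receptor for dying cells, and the fractalkine receptor Cx3cr1 (1.21 against 0.16, 0.39 and -0.39). Syce1 followed another division, not well above background on either array of mice 1 and 3 and at -1.50 and -0.95 in mice 2 and 4.

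Of the fixed lists, 7 held more of these genes than expected (Fisher's exact test, one-sided, adjusted over 32 lists). The test treats genes as independent, although members of a list can move together and mouse 1 lay farthest for 696 of the 900 genes. Its p-values therefore count genes and not mice, and are given as a description only. They were LXR targets and cholesterol efflux (10 of 21 members, adjusted p = 3.29e-07), immediate early genes (8 of 23, 6.48e-05), alternative activation (7 of 17, 6.48e-05), scavenger and phagocytic receptors (8 of 27, 0.000175), neutrophil and granule markers (5 of 10, 0.000290), inflammatory cytokines and chemokines (6 of 17, 0.000430) and osteoclast markers (4 of 13, 0.0110). In mouse 1 the called members were lower for 8 of 10 LXR targets, 5 of 7 alternative activation genes, 6 of 8 scavenger receptors, 5 of 6 inflammatory genes, 4 of 5 neutrophil markers and 4 of 4 osteoclast markers, and higher for 5 of 8 immediate early genes.

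The tests on interferon-stimulated and immediate early genes below, and that on other cell types, were chosen only after the results were seen. The differences between mice did not come from the scaling or from the row of the slide alone. Quantile normalization kept 95.2% of the 900 genes (857), the deposited table called 1813 genes with 832 of them shared, and 753 genes differed between mice 1 and 2, which share a slide row, against 21 between mice 3 and 4 in the other row. Other cell types in the cultures may contribute, since the 4 called osteoclast markers (Acp5, Atp6v0d2, Ctsk and Mmp9) were lower in mouse 1 (adjusted p = 0.0110), while the 4 called macrophage identity genes (Aif1, Cd14, Cx3cr1 and Lyz2) were higher, in a list that did not pass (4 of 28, 0.127). Relative to the mean of the 4 mice, mouse 1 lay at -0.47 for osteoclast, -0.60 for fibroblast and -0.55 for neutrophil markers. It lay at -0.45 for erythroid cells and megakaryocytes, -0.06 for dendritic cells and 0.10 for lymphocytes. Of these marker lists, only those of osteoclasts and neutrophils passed. The osteoclast list was picked for this test after the values were seen, the most enriched marker list, of neutrophils (0.000290), had members both ways (4 lower, Mmp8 higher), and 13 of the 14 osteoclast markers were above background in these cultures, with Ctsk at 2.62 and Acp5 at 2.63 in mouse 1. A different state of the macrophages stays open. Apart from the markers of other cell types, no biological explanation was tested, as the labels give the mice no group.

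The shift of interferon-stimulated genes may rest on 1 mouse and on members that move together. The inter-gene correlation was estimated at 0.62, and with it the adjusted p was 0.956. The largest mean shift, in mouse 3, was 2.65 times the next largest, and without mouse 3 the adjusted p was 0.573. Chance, slide column and an effect of the siRNA stay open.

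For immediate early genes the estimated correlation was 0.0115, which argues against a list whose members all move together. Such an average does not exclude groups of members that move opposite ways. In mouse 1, Egr1 (0.73) and Nr4a1 (0.69) lay above the mean of the 4 mice, and Egr2 (-0.80) and Myc (-0.75) below it. With the estimated correlation, camera also falls back on the few degrees of freedom of 8 arrays, and its adjusted p was 0.701. The largest mean shift, in mouse 4, was 1.42 times the next, and the mean shift was negative in each mouse. The call was lost without mouse 4 (adjusted p = 0.148) and without mouse 3 (0.106). The median was then -0.074 and -0.077, against -0.063 with all mice. These sizes argue against 1 mouse carrying the size of the shift. The call itself depends on which mice are kept, so the test of 1 mouse carrying it was undecided. Chance, slide column, which follows the siRNA group, and an effect of the siRNA stay open.

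Other splits of the 8 arrays were compared with the real one. The real split called 0 genes, a count that all 35 splits into 4 and 4 reach by definition, so this count decides nothing, and the highest other count was 4. For the lists, 33 of 35 splits called 2 or more, as the real one did, and the highest other count was 15, so chance cannot be excluded. The splits with the highest counts of genes keep both arrays of every mouse together, which points to the mice as the main structure of the samples. Among the 8 splits that part every pair, 1 called 11 genes or more with the mouse as a random block, namely the real one, and the highest other called 8. That other split sets slide columns 1 and 4 against columns 2 and 3, so it also follows the position on the slide. The real split sets columns 1 and 3 against 2 and 4, so slide position cannot be set aside for its 11 genes. With the fixed block the real split had 1777 genes at an unadjusted p under 0.05 against at most 1363 in the others, and 4 lists against at most 7, and without a block it had 654 genes against at most 695. These 8 splits are too few for a share under 0.05.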
